A study of Homo sapiens with 12 samples.

How the data were processed

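PolyA RNA of hTERT-RPE1 cells, a retinal pigment epithelial line immortalized with telomerase, was sequenced in 12 libraries. Cells received 20 nM of a negative-control siRNA (siNeg), an siRNA against CENPF (siCENPF), an siRNA against FOXM1 (siFOXM1) or both siRNAs together (siCENPF+siFOXM1), and were collected 48 hours later, per the labels' protocols. Each group had 3 libraries, numbered 1 to 3 in the labels. PolyA RNA was isolated and libraries made with NEBNext kits (Ultra II for the libraries), per the labels. The strand setting used for counting is not given in the sources used here. The siRNA sequences, and whether each reagent was 1 duplex or a pool, are likewise not given. Whether cells given both siRNAs received 20 nM of each or in total is not given either.

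Per the submitters' processing notes, the authors used bcl2fastq, Trimmomatic, TopHat and edgeR with the hg38 genome, with no versions given. The authors' main table holds normalized counts for 14862 genes, a signal on a count scale that the authors brought to similar library sizes by a method not given in the sources used here. Its column sums run from 1.85e+07 to 1.98e+07, and each library's values stay within 0.299% of its CPM times 1 factor for 99% of the genes compared. The authors deposited a table of FPKM for 60279 genes, of which 30854 stand at 0 in all libraries. The authors also deposited 3 edgeR tables, of siCENPF, siFOXM1 and siCENPF+siFOXM1 against siNeg, with CPM per library, log2 fold changes, a likelihood ratio score and a p-value per gene, per the file headers. These tables hold 14306, 14393 and 14336 genes. Gene positions on hg38 come from the same tables. Symbols came from the authors' tables for 14202 genes of the normalized count table and from the gene annotation of the reference for 601, and 59 genes had no symbol.

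Depth was recovered from the deposited CPM, whose values are whole multiples of what 1 read is worth. In every library 100% of the values gave whole reads within a tolerance of 0.01 reads. Reads worked out from CPM and from FPKM differed at 0 of 258210 values. Reads counted in genes numbered 16079871, 13681255 and 35411230 in the siNeg libraries 1 to 3, 13894831, 14097515 and 31302177 in siCENPF, 13671250, 13907867 and 17968360 in siFOXM1, and 15112858, 15801838 and 17018969 in siCENPF+siFOXM1. Mitochondrially encoded genes took 2.05% to 2.93% of the reads. Recovered reads covered all 12 libraries for 14556 genes.

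Before the data were examined, the groups, the tests, the alternatives, the gene lists and the rule for naming genes were fixed. The main test was limma (version 3.58.1, R 4.3.3) with a trend and robust variance moderation on log2(normalized count + 1). It was fitted to all 12 libraries with 4 group means and no further term. Genes with at least 10 normalized counts in at least 3 libraries were kept, which left 14857. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. Every fold change is on the log2(value + pseudocount) scale, which understates the change of genes with low values. The comparisons were each siRNA and both siRNAs together against siNeg, both siRNAs against each single siRNA, the interaction (whether both siRNAs differed from the sum of the single effects) and an F test over the 4 groups.

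Named genes were CENPF and FOXM1, then, for each comparison against siNeg, the 10 rising and 10 falling genes with the largest log2 fold change among those past the threshold. Such genes needed a mean of at least 100 normalized counts, no overlap between the libraries of the 2 groups and an official-style symbol. For the other comparisons 5 genes per direction were taken by the same rule. From each fixed list up to 4 members with the smallest adjusted p were named. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over 138 tests (23 lists in 6 comparisons), and again with an estimated correlation and with fry. Neither target belongs to a list. The lists were centromere chromatin and CENP-A loading, inner kinetochore, outer kinetochore, kinetochore corona and motors, spindle checkpoint, chromosomal passenger complex and shugoshins, cohesin and condensin, FOXM1 targets of textbook standing, G2/M phase, S phase, p53 targets, interferon-stimulated genes, senescence-associated secretory genes, extracellular matrix, YAP/TAZ targets, integrated stress and unfolded protein response, cholesterol synthesis and primary cilium. Further lists held mitochondrially encoded mRNAs as a sign of RNA quality, markers of differentiated retinal pigment epithelium, and markers of 3 other kinds of cell (keratinocyte or carcinoma, blood and endothelial, neural). Lists overlap: 18 of the 24 FOXM1 targets stand in another list too.

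Replicate numbers in the labels were checked for pairing. The correlation of deviations from the group means, across genes, was 0.272 to 0.639 in the 18 pairs of libraries with the same number and -0.510 to 0.0248 in pairs with other numbers. All 12 libraries correlated best with a library of their own number. The first principal component took 36.9% of the variance, 93.8% of it between replicate numbers. By the rule fixed for this check (every same-number pair above 0.1) the numbers pair the libraries, although no label says what a number stands for. The median residual SD on the log2 scale was 0.190 without and 0.119 with the replicate number as a block, and blocked values are given beside counts of genes called and beside printed genes and lists that passed only with it.

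Alternatives were pseudocounts of 0.1 and 5, no filter, a minimum of 100, rescaling by TMM or median of ratios, the FPKM table (pseudocount 0.5), limma without trend and robust moderation, a fit to the compared libraries alone, a log2 fold change over 1, the replicate block and each library left out in turn. The edgeR quasi-likelihood test (4.0.16) and DESeq2 (1.42.0) were run on the recovered reads. Libraries of a group were compared before averaging and none matched another within sampling noise. The tests were first tested on simulated data for siFOXM1 against siNeg, drawn for 14555 genes with 50 changed genes per fold. Without the block limma recovered 52% of genes changed 1.5-fold, 80% at 2-fold and 98% at 4-fold, and called 0 unchanged genes. With the block it recovered 90%, 100% and 100%, and called 11 unchanged genes. For siFOXM1 against siNeg camera called the changed list and 0 of 20 random lists. The random lists held unrelated genes with counts drawn gene by gene, so this says little about lists whose genes vary together.

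Words of 7 bases in annotated 3' UTRs were searched for sites that an siRNA could bind through its seed, the bases near its 5' end that pair with off-target transcripts. The search covered the 11708 tested genes with an annotated 3' UTR of at least 50 bases, 78.8% of all tested genes and 98.0% of the 11727 protein-coding ones. A word was chosen on one set of the genes and its effect measured on the rest. In simulations over the 11708 genes an effect of -0.05 was found in 10 of 10 runs, an effect of -0.02 in 0 of 10 and no effect in 0 of 10. The simulated words were common ones, so these runs do not give the power for words that few genes hold. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.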

Results

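Knockdown of CENPF, which encodes a kinetochore and nuclear matrix protein, and of FOXM1, which encodes a transcription factor of G2 and M phase genes, was measured in hTERT-RPE1 cells in 12 libraries. The series addresses how each protein contributes to transcription of centromere and kinetochore genes. Values are normalized counts, given as mean ± SD over 3 libraries, and fold changes are on the log2(value + pseudocount) scale. Nothing in the labels says that replicates came from separate cultures, so every p-value measures only the spread between these samples.

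Both targeted transcripts were lower in every library given their siRNA. CENPF (ENSG00000117724, chromosome 1, 214603195 to 214664588, plus strand) stood at 7797, 9537 and 7993 normalized counts in siNeg libraries 1 to 3. It stood at 893, 827 and 1017 with siCENPF, at 7567, 7448 and 7723 with siFOXM1, and at 1360, 1360 and 1284 with both siRNAs. FOXM1 (ENSG00000111206, chromosome 12, 2857681 to 2877040, minus strand) stood at 4186, 4438 and 4763 in siNeg and at 3893, 3394 and 4258 with siCENPF. It stood at 732, 491 and 816 with siFOXM1 and at 729, 816 and 822 with both.

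CENPF fell with siCENPF (log2 fold change -3.21, SE 0.09, limma adjusted p = 5.56e-10), to 10.8% of siNeg, and with both siRNAs (-2.65, SE 0.09, adjusted p = 6.41e-09), to 15.9%. With siFOXM1 its log2 fold change was -0.15 (SE 0.09, limma adjusted p = 0.802). FOXM1 fell with siFOXM1 (log2 fold change -2.74, SE 0.15, limma adjusted p = 3.30e-06), to 14.9% of siNeg, and with both siRNAs (-2.50, SE 0.15, adjusted p = 5.22e-06), to 17.7%. With siCENPF its log2 fold change was -0.22 (SE 0.15, limma adjusted p = 1.00).

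**Figure D1:**
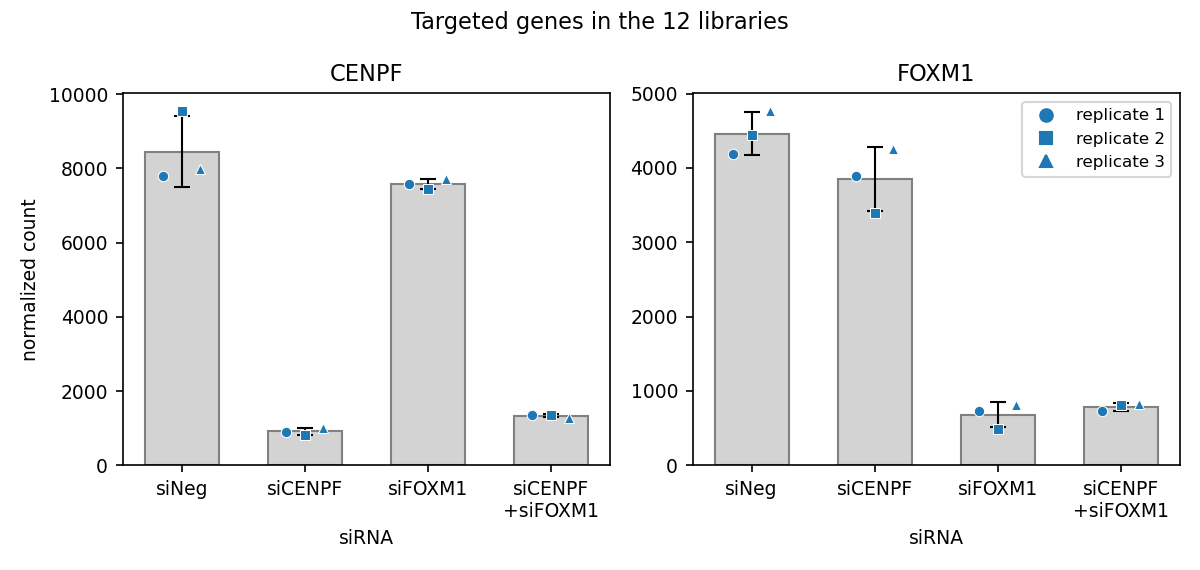
Normalized counts of CENPF and FOXM1 in each library, by group; points are libraries, bars are means of 3 and lines their SD. CENPF averaged 8442 ± 953 in siNeg, 913 ± 96.5 with siCENPF, 7579 ± 138 with siFOXM1 and 1335 ± 44.0 with both; FOXM1 averaged 4462 ± 289, 3848 ± 434, 680 ± 168 and 789 ± 52.2.

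The comparison of siCENPF with siNeg asks what changed when CENPF was depleted. LMLN, DDAH1, SRPR, VWA9 and HDAC1 rose, and DPH1, SOX11, OSTM1 and HIF1AN fell. The rising genes given here were also called higher with siFOXM1 and with both siRNAs, by similar amounts. Their rise was therefore not particular to CENPF depletion. DDAH1, an enzyme that degrades asymmetric dimethylarginine, rose 2.14-fold, from 3403 ± 566 to 7219 ± 344 (log2 fold change 1.10, SE 0.12, limma adjusted p = 0.00159, n = 3 libraries per group). HIF1AN, the asparaginyl hydroxylase that acts on HIF-1 alpha, fell by log2 0.75 (SE 0.08, limma adjusted p = 0.00131), from 2551 ± 207 to 1510 ± 6.52. In all, limma called 50 of 14857 genes, 32 higher and 18 lower, and 671 (425 higher, 246 lower) with the replicate number as a block. Of the 32 called higher without the block, 23 were called higher with siFOXM1 too.

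LMLN (ENSG00000185621, chromosome 3, 197960200 to 198043720) rose from 77.3 ± 6.75 to 206 ± 26.8 (log2 fold change 1.40, limma adjusted p = 0.00163). SRPR (current symbol SRPRA, ENSG00000182934), a subunit of the receptor of the signal recognition particle, rose from 1894 ± 257 to 3698 ± 499 (log2 fold change 0.97, limma adjusted p = 0.00287). HDAC1 (ENSG00000116478, chromosome 1, 32292086 to 32333635), a histone deacetylase, rose from 751 ± 33.7 to 1272 ± 43.2 (log2 fold change 0.76, limma adjusted p = 0.00163). VWA9 (current symbol INTS14) rose by log2 0.76 and WDR18 by 0.77 (limma adjusted p = 0.00159 and 0.00253). CDH10 rose by log2 1.20 and KIAA1467 (current symbol FAM234B) by 0.89 (limma adjusted p = 0.0271 and 0.0186). Annotated 3' UTRs of DDAH1, LMLN, SRPR, VWA9, WDR18 and CDH10 hold the word AGCAACC, which 34.1% of the searched genes higher in all 3 knockdown groups share, against 8.03% of all searched genes. Those of HIF1AN and SOX11, which fell, hold it too, and those of KIAA1467, HDAC1 and H4C9, which rose, do not. H4C9 and HIST1H2BK rose by log2 1.21 and 1.11 (limma adjusted p = 0.0335 and 0.0175), and reads of such multigene histone families are uncertain in their assignment. On the FPKM table LMLN stood at log2 0.51, CDH10 at 0.67, KIAA1467 at 0.42 and H4C9 at 1.09, and none of these 4 passed (limma adjusted p = 0.224, 0.202, 0.254 and 0.0703). FPKM values, here and below, come from the same reads, and their pseudocount of 0.5 understates the change of genes with low values. By edgeR on recovered reads CDH10 stood at 1.22 and H4C9 at 1.18 (adjusted p = 0.0546 and 0.0627).

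DPH1 (ENSG00000108963, chromosome 17, 2030110 to 2043430) fell by log2 1.10 (limma adjusted p = 0.0163), from 195 ± 21.3 to 91.0 ± 16.2, and did not pass on the FPKM table (log2 fold change -0.44, adjusted p = 0.426). SOX11 (ENSG00000176887, chromosome 2, 5692667 to 5701385), a developmental transcription factor, fell by log2 1.05 (limma adjusted p = 0.00287), from 565 ± 46.3 to 273 ± 23.5. OSTM1 fell by log2 0.87 (limma adjusted p = 0.0239), from 1280 ± 174 to 699 ± 95.6. FAM217B, HDAC4, C3orf38, ATL3 and TMEM245 fell by log2 1.04, 0.72, 0.69, 0.64 and 0.56. Annotated 3' UTRs of HIF1AN, OSTM1 and C3orf38 hold the word AGCGCTA, for which a seed effect of the CENPF siRNA stays open. Those of DPH1, SOX11, FAM217B, HDAC4, ATL3 and TMEM245 do not hold it. Of the 20 genes taken by the naming rule for this comparison, 9 kept their call with each library left out in turn. DPH1, OSTM1, FAM217B, HDAC4, C3orf38, ATL3, TMEM245, CDH10, KIAA1467, H4C9 and HIST1H2BK each lost it without at least 1 library.

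Of the fixed lists, 4 stood higher and 7 lower with siCENPF by camera. S phase genes had a median log2 fold change of -0.21, with 41 of 43 below 0 (camera adjusted p = 4.28e-10; adjusted p = 0.962 with an estimated correlation). Their medians were similar in the other knockdown groups, so this shift was not particular to CENPF depletion. G2/M genes had a median of -0.10, with 50 of 53 below 0 (adjusted p = 7.77e-07; adjusted p = 0.976 with an estimated correlation). FOXM1 targets had a median of -0.11, with 23 of 24 below 0 (adjusted p = 0.00025; adjusted p = 0.976 with an estimated correlation). No single member of these 3 lists passed limma, over all genes or adjusted over the list alone; BLM stood at log2 -0.39 and AURKA at -0.35 (limma adjusted p = 0.226 and 0.378 without, 0.00740 and 5.78e-05 with the block). With the block, 14 S phase, 6 G2/M and 3 FOXM1 target genes fell.

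Of the centromere and kinetochore lists, 4 stood lower with siCENPF by camera. Their median log2 fold changes were -0.16 for 13 outer kinetochore genes (camera adjusted p = 0.00552), -0.16 for 6 genes of the passenger complex and shugoshins (0.00424), -0.08 for 16 inner kinetochore genes (0.0257) and -0.10 for 22 cohesin and condensin genes (0.00424). With an estimated correlation the adjusted p was 0.962 for the outer kinetochore and passenger lists and 0.976 for the inner kinetochore and cohesin lists. None of their members passed limma; ZWINT stood at log2 -0.26 (adjusted p = 0.725; with the block 0.00517), CENPU at -0.22 (0.906; 0.0353) and INCENP at -0.18 (0.902). The list of centromere chromatin and CENP-A loading had a median of -0.09 (camera adjusted p = 0.304) and the spindle checkpoint -0.11 (0.242). The kinetochore corona, with a median of -0.10, passed with the block (camera adjusted p = 0.139 without, 0.0420 with it, 0.348 with it and an estimated correlation).

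Among the lists that stood higher with siCENPF, 13 extracellular matrix genes had a median of 0.15 (camera adjusted p = 0.00562; adjusted p = 0.962 with an estimated correlation). The collagen gene COL4A1 rose by log2 0.57 (SE 0.09, limma adjusted p = 0.0170), and 3 members rose adjusted over the list alone. COL4A1 was called higher in every knockdown group, by similar amounts. Senescence-associated secretory genes had a median of 0.28 (camera adjusted p = 0.00424; adjusted p = 0.962 with an estimated correlation) and YAP/TAZ targets 0.03 (0.0499; adjusted p = 0.976 with an estimated correlation). The 13 mitochondrially encoded mRNAs, a sign of RNA quality, stood at a median of 0.11 (0.0463; adjusted p = 0.976 with an estimated correlation). Integrated stress genes (median 0.20) passed with the block only (camera adjusted p = 0.0769 without, 1.81e-05 with it, 0.373 with it and an estimated correlation), as did cholesterol synthesis (median 0.09; 0.337, 0.0156 and 0.576).

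Medians of the other lists with siCENPF were 0.04 for p53 targets, -0.20 for interferon-stimulated genes, 0.05 for primary cilium and 0.00 for retinal pigment epithelium markers (camera adjusted p = 0.599, 0.733, 0.991 and 0.568). For the cilium the median was above and the mean, at 0.00, just below 0. Keratinocyte, blood and endothelial, and neural markers, of which 3, 2 and 3 were measured, had medians of -0.22, -0.47 and -0.08 (camera adjusted p = 0.302, 0.305 and 0.799). The replicate libraries of siCENPF and siNeg did not overlap for 9.31% of genes, where chance gives 10% if libraries are unpaired and simulations of unchanged groups that keep the differences between replicate numbers gave 3.81%. Without siNeg library 2, limma called 21 genes in place of 50.

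The comparison of siFOXM1 with siNeg asks what changed when FOXM1 was depleted. TMEM71, NEURL1B, ITFG2, CDKN3 and THOC7 fell, and LMLN, DDAH1, SRPR, MPRIP and HDAC1 rose. Each of these rising genes was also called higher with siCENPF, by a similar amount, so its rise was not particular to FOXM1 depletion. CDKN3, a phosphatase of CDK1 and CDK2 that peaks late in the cell cycle, fell from 1157 ± 170 to 458 ± 59.1 (log2 fold change -1.33, SE 0.19, limma adjusted p = 0.00571, n = 3 libraries per group). TMEM71 (ENSG00000165071, chromosome 8, 132685007 to 132760712) fell from 325 ± 33.7 to 55.5 ± 6.62 (log2 fold change -2.53, SE 0.21, limma adjusted p = 7.08e-05). In all, limma called 98 genes, 41 higher and 57 lower, and 1295 (666 higher, 629 lower) with the block.

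NEURL1B (ENSG00000214357, chromosome 5, 172641266 to 172691540), a ubiquitin ligase of the Notch pathway, fell from 222 ± 48.9 to 40.0 ± 3.71 (log2 fold change -2.42, limma adjusted p = 0.000668). ITFG2 (ENSG00000111203, chromosome 12, 2812622 to 2859791, plus strand) fell from 1192 ± 117 to 379 ± 24.0 (log2 fold change -1.65, SE 0.12, limma adjusted p = 3.18e-05). Its annotated exons share 781 bases with those of FOXM1 on the opposite strand, and the strand setting of the counting is not given, so this value is uncertain. THOC7, a subunit of the THO mRNA export complex, fell by log2 1.21 (limma adjusted p = 0.000479) and CNTRL, which encodes centriolin, by 1.12 (adjusted p = 0.00293). RMND5A, B3GNT5 and SMIM13 fell by log2 1.08, 1.06 and 1.04.

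LMLN rose with siFOXM1 by log2 1.57, HIST1H2BK by 1.23, DDAH1 by 1.02, KIAA1467 by 0.91, SRPR by 0.89, VWA9 by 0.80 and HDAC1 by 0.77 (limma adjusted p = 0.000479, 0.00638, 0.000811, 0.0113, 0.00404, 0.000490 and 0.000668). MPRIP, which encodes a myosin phosphatase partner, rose from 5140 ± 301 to 8663 ± 352 (log2 fold change 0.75, limma adjusted p = 0.000747). UBE2D1 and PRUNE (current symbol PRUNE1) rose by log2 0.73 and 0.71 (limma adjusted p = 0.0258 and 0.0272). Annotated 3' UTRs of LMLN, DDAH1, SRPR, VWA9, MPRIP and UBE2D1 hold the word AGCAACC, and those of KIAA1467, HDAC1 and PRUNE do not. On the FPKM table LMLN stood at log2 0.61, KIAA1467 at 0.45, PRUNE at 0.38 and CNTRL at -0.56, and none of these 4 passed (limma adjusted p = 0.0678, 0.122, 0.177 and 0.0829). Of the 20 genes taken by the naming rule for this comparison, 15 kept their call with each library left out in turn, and KIAA1467, UBE2D1, PRUNE, B3GNT5 and SMIM13 did not.

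Of the 24 FOXM1 targets, 4 fell with siFOXM1 and 20 did not pass limma. The cyclin genes CCNA2 and CCNB1 fell by log2 0.63 and 0.67 (limma adjusted p = 0.00540 and 0.0113), and the mitotic kinase NEK2 and the kinesin KIF20A by 0.84 and 0.74 (limma adjusted p = 0.0280 and 0.0363). Adjusted over the list alone 5 fell and 0 rose; with the block 9 fell and 1 rose. The list's median was 0.01, with 12 members above and 12 below 0, while its mean was -0.15 and camera placed it lower (adjusted p = 0.0160; adjusted p = 0.976 with an estimated correlation). S phase genes stood at a median of -0.22, with 43 of 43 below 0 (camera adjusted p = 5.35e-10; adjusted p = 0.962 with an estimated correlation), and 22 of them fell with the block. This median was close to that with siCENPF, so the shift was not particular to FOXM1 depletion.

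Cholesterol synthesis genes stood at a median of 0.29, with 18 of 18 above 0 (camera adjusted p = 0.00198; adjusted p = 0.976 with an estimated correlation). None passed limma singly, and 13 rose with the block; MSMO1 stood at log2 0.75 (limma adjusted p = 0.548 without, 2.50e-07 with the block). Extracellular matrix genes stood at 0.26 (camera adjusted p = 0.00424; adjusted p = 0.962 with an estimated correlation), and COL4A1 rose by log2 0.49 (limma adjusted p = 0.0258). Mitochondrially encoded mRNAs, at a median of 0.13, passed with the block only (camera adjusted p = 0.0723 without, 0.000450 with it, 0.442 with it and an estimated correlation).

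In the centromere and kinetochore lists, 1 gene fell with siFOXM1: NDE1, a partner of dynein and CENPF, by log2 0.85 (SE 0.09, limma adjusted p = 0.000556). CENPA, the centromeric histone H3 variant, stood at log2 -0.56 and passed with the block only (limma adjusted p = 0.573 without, 0.000224 with it). CENPB stood at -0.13 (limma adjusted p = 0.815). CENPU stood at -0.33, NUF2 at -0.37 and TTK at 0.43, and all 3 passed with the block only (limma adjusted p = 0.285, 0.680 and 0.464 without, 0.000740, 0.000150 and 4.11e-05 with it). The spindle checkpoint, at a median of 0.12, passed with the block only (camera adjusted p = 0.175 without, 0.0292 with it, 0.397 with it and an estimated correlation). Camera adjusted p was 0.611 for CENP-A loading (median -0.08), 0.984 for the inner kinetochore (0.03), 0.228 for the outer kinetochore (-0.11), 0.823 for the corona (0.01), 0.621 for the passenger complex (0.04) and 0.262 for cohesin and condensin (-0.03).

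G2/M genes had a median of 0.03 and a mean of -0.03 with siFOXM1 (camera adjusted p = 0.897), and NEK2 was the 1 of 53 that passed. PTPN14, a YAP regulator, fell by log2 0.49 and the cilium motor gene KIF3B rose by 0.40 (limma adjusted p = 0.0237 and 0.0235). Interferon-stimulated genes (median -0.52) passed with the block only (camera adjusted p = 0.405 without, 0.000602 with it, 0.576 with it and an estimated correlation). Libraries numbered 1 stand apart in this list, with a median deviation from the group means of 2.23 against -1.08 and -1.20 in numbers 2 and 3. The list's median log2 change with siFOXM1 was -1.02, -0.27 and -0.04 within numbers 1 to 3. Other medians were 0.01 for p53 targets, 0.04 for senescence-associated secretory genes, -0.10 for integrated stress and -0.16 for retinal pigment epithelium markers (camera adjusted p = 0.549, 0.646, 0.661 and 0.132). Non-overlapping libraries were found for 13.4% of genes, where chance gives 10% (3.81% with the numbers' differences kept). Without siFOXM1 library 3, limma called 34 genes in place of 98.

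**Figure D2:**
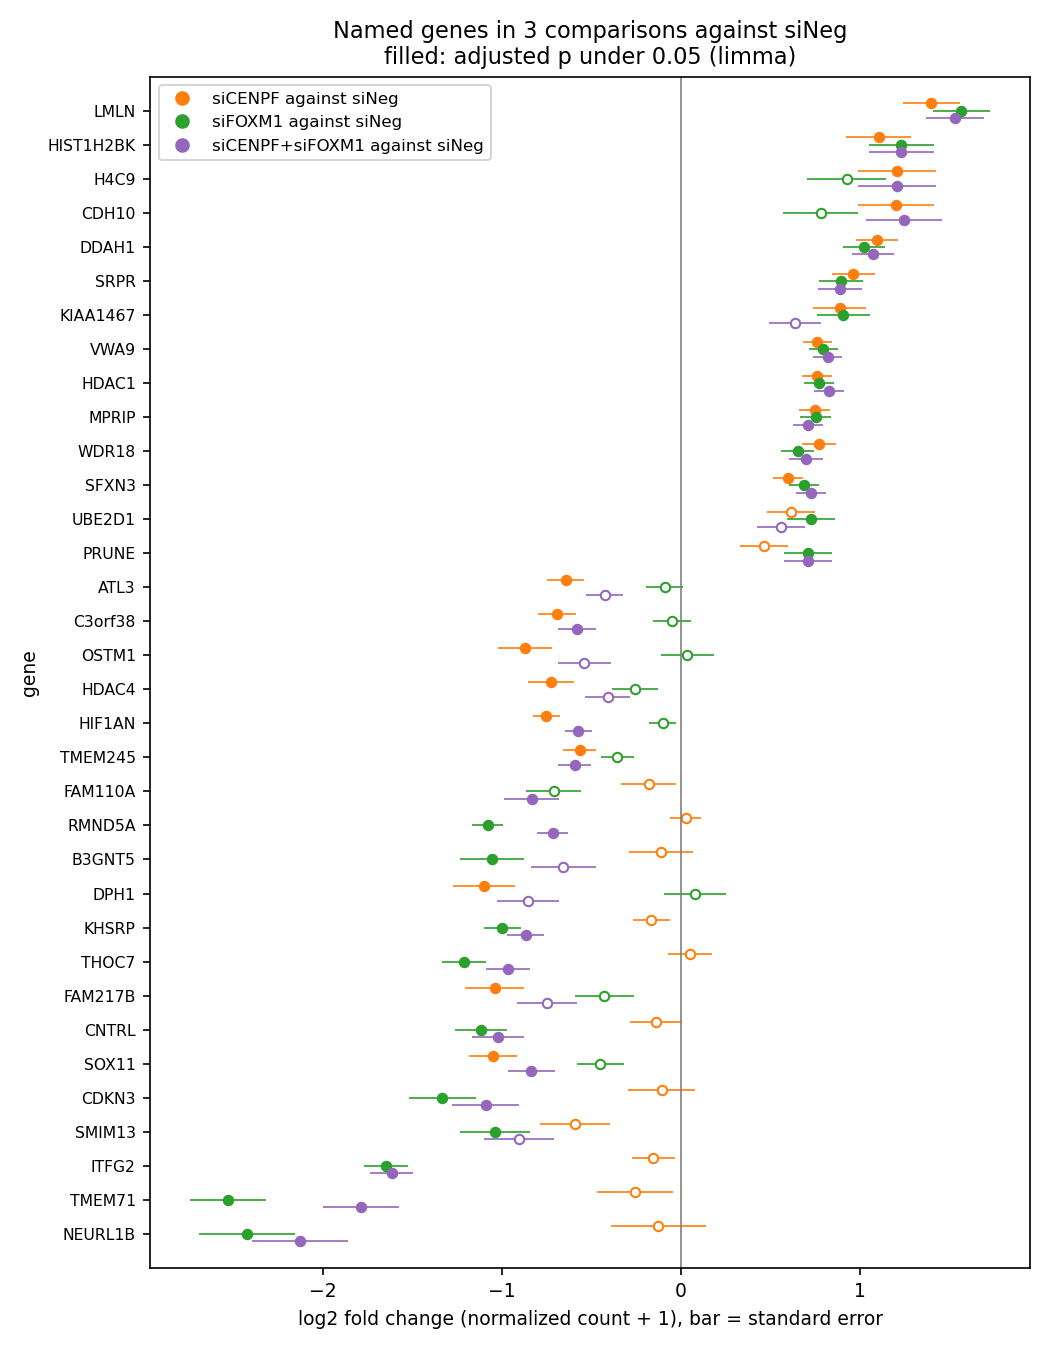
Log2 fold change against siNeg of named genes in the 3 knockdown groups; points are estimates of limma, filled where the adjusted p is under 0.05, and lines their standard errors (n = 3 libraries per group). DDAH1 stood at 1.10, 1.02 and 1.07 with siCENPF, siFOXM1 and both; ITFG2 at -1.65 with siFOXM1.

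The comparison of both siRNAs with siNeg asks what changed when both proteins were depleted. DDAH1 (log2 fold change 1.07), SRPR (0.89), HDAC1 (0.83) and LMLN (1.53) rose, and NEURL1B (-2.13), TMEM71 (-1.79), ITFG2 (-1.62) and CDKN3 (-1.09) fell. The rising genes given here were called higher with each single siRNA too. KHSRP, which encodes a KH-type RNA-binding protein, fell from 6061 ± 411 to 3320 ± 148 (log2 fold change -0.87, SE 0.10, limma adjusted p = 0.00165, n = 3 libraries per group). In all, limma called 68 genes, 34 higher and 34 lower, and 1174 (621 higher, 553 lower) with the block.

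SFXN3 rose by log2 0.73, VWA9 by 0.82, PRUNE by 0.71 and HIST1H2BK by 1.23 (limma adjusted p = 0.00165, 0.000670, 0.0352 and 0.00719), and CDH10 rose 2.38-fold (adjusted p = 0.0188). Annotated 3' UTRs of SFXN3, VWA9 and CDH10 hold the word AGCAACC, and that of PRUNE does not. THOC7, CNTRL, SOX11 and FAM110A fell by log2 0.97, 1.02, 0.84 and 0.83 (limma adjusted p = 0.00228, 0.00583, 0.0127 and 0.0301). On the FPKM table LMLN stood at log2 0.59, CDH10 at 0.72, PRUNE at 0.39, CDKN3 at -0.99, CNTRL at -0.52 and FAM110A at -0.50, and none of these 6 passed (limma adjusted p = 0.107, 0.117, 0.216, 0.0945, 0.146 and 0.0756). Of the 20 genes taken by the naming rule, 12 kept their call with each library left out in turn; CDH10, CDKN3, FAM110A, HIST1H2BK, PRUNE and SOX11 were among those that did not. Without siNeg library 2, limma called 30 genes in place of 68. Non-overlapping libraries were found for 12.9% of genes, where chance gives 10% (3.81% with the numbers' differences kept).

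S phase genes stood at a median of -0.26 with both siRNAs, with 43 of 43 below 0 (camera adjusted p = 1.92e-15; adjusted p = 0.962 with an estimated correlation), and 29 fell with the block. FOXM1 targets stood at -0.13 (camera adjusted p = 0.000101; adjusted p = 0.976 with an estimated correlation). Of these, 3 fell: CCNA2, CCNB1 and NEK2, by log2 0.58, 0.67 and 0.82 (limma adjusted p = 0.0104, 0.0140 and 0.0461), and 5 fell adjusted over the list alone. NEK2 and the cytoskeletal gene GAS2L3 (log2 fold change -0.47, limma adjusted p = 0.0475) fell among G2/M genes, whose median was -0.03 (camera adjusted p = 0.0272; adjusted p = 0.976 with an estimated correlation). Cohesin and condensin genes stood at -0.08 (camera adjusted p = 0.0272; adjusted p = 0.976 with an estimated correlation). NDE1 fell by log2 0.74 (limma adjusted p = 0.00200).

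Extracellular matrix genes stood at 0.30 (camera adjusted p = 0.00424; adjusted p = 0.962 with an estimated correlation), and COL4A1 rose by log2 0.56 (limma adjusted p = 0.0147). Cholesterol synthesis genes stood at 0.25, with 18 of 18 above 0 (camera adjusted p = 0.00641; adjusted p = 0.976 with an estimated correlation), and 10 rose with the block. Mitochondrially encoded mRNAs stood at 0.07 (camera adjusted p = 0.337). With the block only, senescence-associated secretory genes (median 0.18; camera adjusted p = 0.0980 without, 0.00954 with it, 0.373 with it and an estimated correlation) and interferon-stimulated genes (-0.67; 0.181, 4.61e-06 and 0.494) passed. Within numbers 1 to 3, of which number 1 stands apart in the interferon list, that list's median log2 change was -0.97, -0.13 and -0.73. The cytokine gene IL1B stood at log2 1.22 and passed with the block only (limma adjusted p = 0.605 without, 3.71e-10 with it).

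Both siRNAs against siFOXM1 asks what CENPF depletion added where FOXM1 was depleted. The dose of each siRNA in the group given both is not stated. The comparison therefore cannot separate CENPF depletion from a change in the dose of the FOXM1 siRNA. CENPF was the 1 gene that limma called, with a log2 fold change of -2.50 (SE 0.09, adjusted p = 1.35e-08), to 17.6% of its level with siFOXM1, and 44 genes (20 higher, 24 lower) passed with the block. G2/M genes stood at a median of -0.06, with 40 of 53 below 0 (camera adjusted p = 0.00424; adjusted p = 0.976 with an estimated correlation). S phase genes stood at -0.06, with 35 of 43 below 0 (camera adjusted p = 0.0463; adjusted p = 0.986 with an estimated correlation). AURKA, the mitotic kinase, stood at log2 -0.28 and passed with the block only (limma adjusted p = 1.00 without, 0.00917 with it). Non-overlapping libraries were found for 6.79% of genes, where chance gives 10% (3.81% with the numbers' differences kept).

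With the block only, 4 lists stood higher with both siRNAs than with siFOXM1 and 4 lower. Those higher were senescence-associated secretory genes (camera adjusted p = 0.0986 without, 0.00257 with the block, 0.348 with it and an estimated correlation), YAP/TAZ targets (0.240, 0.0244 and 0.442), integrated stress (0.279, 0.0474 and 0.606) and retinal pigment epithelium markers (0.111, 0.0292 and 0.348). Those lower were the inner kinetochore (0.0504, 0.0406 and 0.521), the spindle checkpoint (0.191, 0.0446 and 0.442), FOXM1 targets (0.122, 0.0159 and 0.397) and mitochondrially encoded mRNAs (0.225, 0.00874 and 0.526).

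Both siRNAs against siCENPF asks what FOXM1 depletion added where CENPF was depleted. FOXM1 fell (log2 fold change -2.28, SE 0.15, limma adjusted p = 3.16e-05). NEURL1B, TMEM71, ITFG2 and THOC7 fell by log2 2.00, 1.53, 1.46 and 1.02 (limma adjusted p = 0.00988, 0.00988, 0.000136 and 0.00537, n = 3 libraries per group), and NDE1 by 0.66 (adjusted p = 0.00988). Limma called 12 genes, 0 higher and 12 lower, and 217 (64 higher, 153 lower) with the block; 439 genes had an unadjusted p under 0.05, edgeR called 11 and DESeq2 33. CENPF stood 0.55 higher and passed with the block only (limma adjusted p = 0.0619 without, 0.000188 with it). By this estimate CENPF was less depleted with both siRNAs, and the dose of each siRNA in that group is not stated. Differences from siCENPF may therefore partly reflect dose or the level of CENPF, which was not tested. CCNA2 stood at log2 -0.51 and CCNB1 at -0.58, and both passed with the block only (limma adjusted p = 0.0692 and 0.0968 without, 4.87e-07 and 3.29e-07 with it).

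Passenger complex genes stood at a median of 0.13 against siCENPF, with 6 of 6 above 0 (camera adjusted p = 0.00424; adjusted p = 0.962 with an estimated correlation). The spindle checkpoint stood at 0.13 (0.0330; adjusted p = 0.962 with an estimated correlation), G2/M genes at 0.09 (0.0295; adjusted p = 0.976 with an estimated correlation) and cholesterol synthesis at 0.16, with 18 of 18 above 0 (0.0272; adjusted p = 0.976 with an estimated correlation). S phase genes stood at -0.08 (0.0131) and YAP/TAZ targets at -0.08 (0.0437), both with adjusted p = 0.976 with an estimated correlation. With the block only, interferon-stimulated genes (median -0.41; camera adjusted p = 0.225 without, 4.55e-05 with it, 0.526 with it and an estimated correlation), integrated stress (-0.18; 0.0742, 1.96e-05 and 0.373) and mitochondrially encoded mRNAs (-0.07; 0.312, 0.0244 and 0.560) stood lower and primary cilium genes (0.09; 0.0801, 0.0446 and 0.348) higher. Within numbers 1 to 3 the median log2 change of the interferon list was -1.46, -0.05 and 0.07. Without library 3 of both siRNAs, limma called 2 genes in place of 12, and 1 of the 5 genes taken by the naming rule, ITFG2, kept its call with each library left out. NEURL1B did not pass on the FPKM table (log2 fold change -1.09, limma adjusted p = 0.0837). Non-overlapping libraries were found for 7.43% of genes, where chance gives 10% (3.81% with the numbers' differences kept).

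The interaction asks whether both siRNAs together differed from the sum of the single effects. CENPF remained at 15.9% of siNeg with both siRNAs and at 10.8% with siCENPF alone. FOXM1 remained at 17.7% with both and at 14.9% with siFOXM1 alone. The dose of each siRNA in the group given both is not stated. Departures from the sum may therefore partly reflect dose or weaker knockdown, which was not tested. Limma called 0 genes, with 353 at an unadjusted p under 0.05. EdgeR called 0, DESeq2 22 and limma with the block 125 (16 above and 109 below the sum). A gene that stands higher by the same amount in every knockdown group than in siNeg also falls below the sum. Likewise, a gene that stands lower by the same amount in every knockdown group stands above it. S phase genes stood lower by similar medians in every knockdown group, so a difference of siNeg alone could place them above the sum. S phase genes stood above the sum by a median of 0.15, with 40 of 43 above 0 (camera adjusted p = 0.000121; adjusted p = 0.976 with an estimated correlation). Outer kinetochore genes stood above it by 0.14 (0.0194; adjusted p = 0.962 with an estimated correlation), and FOXM1 targets and G2/M genes by 0.08 and 0.07 (0.0463 and 0.0401; adjusted p = 0.976 for both with an estimated correlation). Extracellular matrix genes stood at -0.12 (0.00653; adjusted p = 0.962 with an estimated correlation) and mitochondrially encoded mRNAs at -0.21 (0.00653; adjusted p = 0.976 with an estimated correlation). With the block only, cohesin and condensin stood above the sum (camera adjusted p = 0.133 without, 0.0432 with it, 0.479 with it and an estimated correlation), and senescence-associated secretory genes (0.196, 0.0202 and 0.373), integrated stress (0.461, 0.00674 and 0.521) and cholesterol synthesis (0.191, 0.000259 and 0.479) below it.

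**Figure D3:**
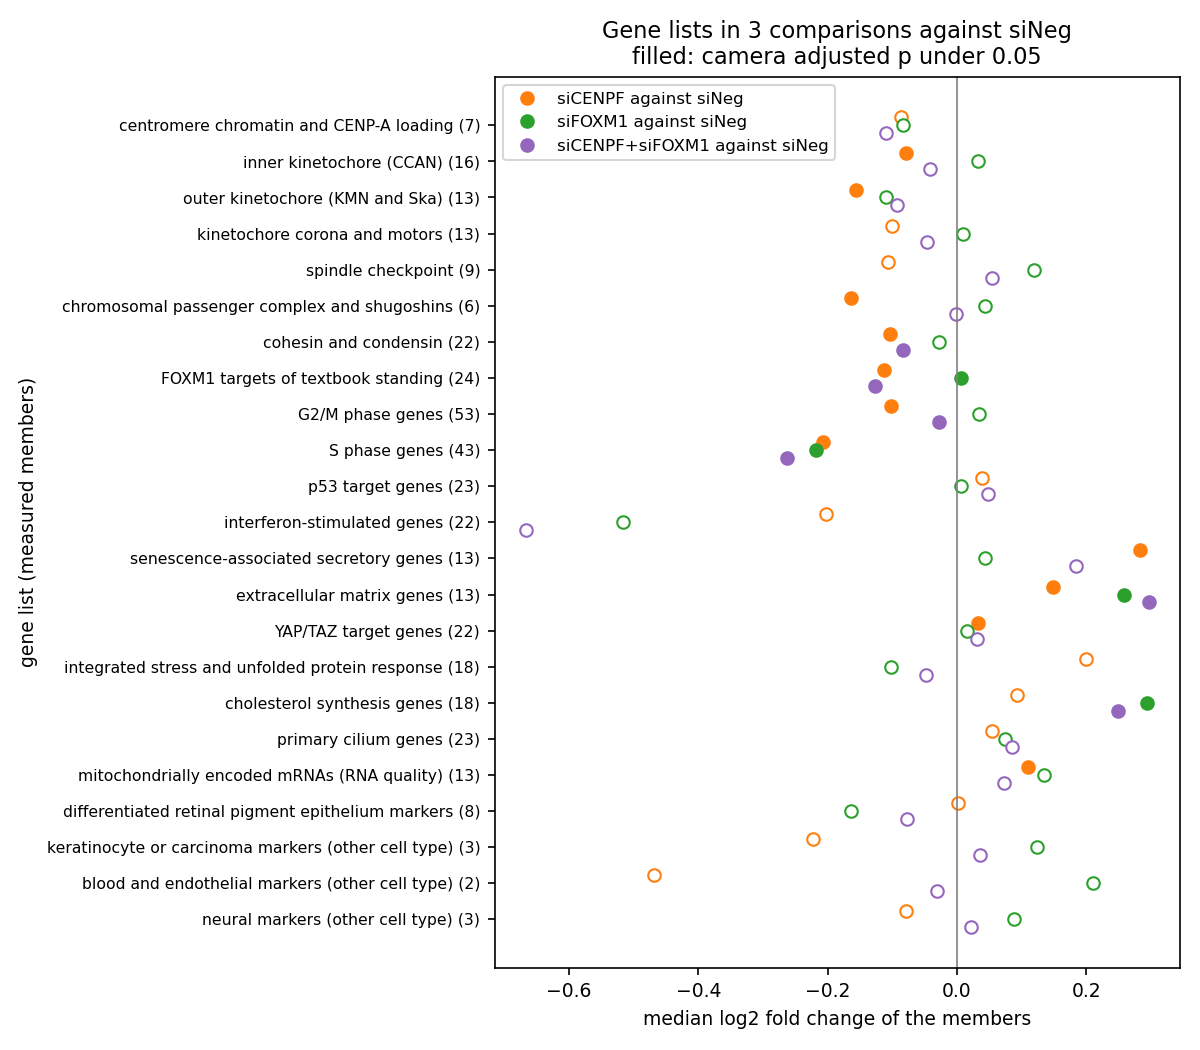
Median log2 fold change of each fixed gene list against siNeg in the 3 knockdown groups, as points filled where the camera adjusted p is under 0.05. S phase genes stood at -0.21, -0.22 and -0.26 with siCENPF, siFOXM1 and both siRNAs.

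Across the 3 comparisons against siNeg, 22 genes were called higher in all 3 and 0 lower in all 3 (227 and 53 with the block). The F test over the 4 groups called 118 genes, and 1758 with the block. Pairs of comparisons share the 3 siNeg libraries, which could not be split because 1 of the parts would hold fewer than 2 libraries, so some of what they share may come from those libraries. Across 14857 genes, which are not independent replicates, log2 fold changes of siCENPF and siFOXM1 correlated at r = 0.484 (0.497 in simulations of unchanged groups with the same controls), with a covariance of 0.0278 (0.0315). For siCENPF and both siRNAs r was 0.595 (0.498) and the covariance 0.0334 (0.0316), and for siFOXM1 and both 0.711 (0.498) and 0.0452 (0.0315). The shared control mean alone sets the simulated r. The spread used in these simulations includes the differences between replicate numbers, which cancel between the groups, so their covariances are too high as a reference. With the spread of the blocked fit, the simulations gave covariances of 0.0163, 0.0164 and 0.0164, which the measured covariances exceed by 0.0114, 0.0170 and 0.0287.

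Genes called higher by both comparisons of a pair numbered 23 for siCENPF and siFOXM1, 26 for siCENPF and both siRNAs, and 29 for siFOXM1 and both. The product of the calls over all genes is 0.0883, 0.0732 and 0.0938, and simulations gave 0. The product treats the comparisons as independent and the simulations hold no changed gene, so neither covers genes that differ in siNeg alone. Genes called lower by both numbered 0, 5 and 26 (products 0.0691, 0.0412 and 0.130, simulations 0). With the block 237, 301 and 430 genes were called higher by both (products 19.1, 17.8 and 27.8) and 55, 131 and 324 lower by both (products 10.4, 9.16 and 23.4), where simulations with the spread of the blocked fit gave 0. With the block 8, 0 and 0 genes were called in opposite directions. By edgeR as the authors ran it, 27, 107 and 80 genes have an adjusted p under 0.05 for siCENPF, siFOXM1 and both siRNAs. Of the 26, 104 and 77 tested here by symbol, limma called 24, 71 and 55, and 26, 104 and 77 with the block.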

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

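With the replicate number as a block, limma found 125 genes for which both siRNAs together differed from the sum of the single effects, by the test of the interaction term; without the block it found 0, with 353 at an unadjusted p under 0.05, edgeR 0 and DESeq2 22. Among named genes, the log2 departure from additivity was -1.43 for LMLN, -1.16 for KIAA1467, -1.11 for HIST1H2BK, -1.05 for DDAH1, -0.97 for SRPR, -0.79 for MPRIP, -0.78 for UBE2D1, -0.74 for VWA9, -0.73 for WDR18, -0.70 for HDAC1 and -0.56 for SFXN3. It was 0.33 for TMEM245, 0.66 for SOX11, 0.70 for CENPF, 0.72 for FAM217B, 0.72 for SMIM13 and 1.00 for TMEM71. None of these 17 genes passed limma without the block, where the lowest adjusted p was 0.0951. Weaker CENPF knockdown or another siRNA dose in the group given both could contribute to such departures, which was not tested. In 100 groupings within replicate numbers, the real one included, 4 called as many genes as the 125 found, with 873 in the highest other. The share lies under 0.05, but the other groupings carry real differences between siRNA groups into the interaction term. They therefore do not stand for an absent interaction, and chance was not excluded. Without the block 0 genes were found, so 100 of 100 regroupings had to call as many and the count says nothing about chance. The highest other called 1276 genes, and the cause was not tested.

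For each comparison of 3 libraries with 3, there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, called as many genes. The real split called 50 genes for siCENPF, 98 for siFOXM1, 68 for both siRNAs, 1 for both against siFOXM1 and 12 for both against siCENPF, and the highest other called 0 in each. With the block, the real split called 671, 1295, 1174, 44 and 217 genes, and other splits that part as many pairs called at most 1, 0, 0, 0 and 0. For the F test over the 4 groups, 9 of 100 regroupings called as many as the 118 genes found (highest other 918), so chance was not excluded. These regroupings mix the replicate numbers, between which 46.4% of genes differed, so their share says little about the siRNA groups. With the block, 1 of 100, the real one, reached 1758 genes (highest other 1313), so chance can be excluded.

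A first pattern is the 227 genes higher in all 3 knockdown groups with the block, with medians of log2 0.36, 0.38 and 0.39; both tests were set before their results were seen. A hypothesis is that the siNeg siRNA lowers transcripts with 3' UTR sites for its seed, which would raise them in every comparison against siNeg. Held-out genes with the chosen word AGCAACC departed from additivity by -0.0939 ± 0.0110 (-8.503 standard errors; 493 genes), and the other set of genes chose the shifted word GCAACCA with -8.01 standard errors. The word stands in 71 of 208 searched pattern genes (34.1%; 8.03% of 11708), among them DDAH1, LMLN, SRPR and VWA9 but not HDAC1, and such genes were higher against siNeg by 0.0902, 0.101 and 0.0971 but differed by -0.00367 and 0.00690 between knockdowns, so an effect of siNeg may account for part of the pattern. Unequal depth cannot account for it alone: 88.11% of the genes (200 of 227) kept their calls when all libraries were thinned to equal reads.

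Another pattern is the 122 genes lower, with the block, in siFOXM1 than in siNeg and in both siRNAs than in siCENPF, with medians against siNeg of log2 -0.51 and -0.42 (-0.03 with siCENPF); the test of shared bases, and the reading of the seed value as open, were chosen after the values were seen. G2/M genes and the related lists hold 9.836% of them (12 of 122), against 1.16% of all genes. The lists are short and leave out genes of the pattern such as CDKN3, which peaks late in the cell cycle. This share therefore cannot tell whether the pattern goes beyond G2/M genes. For a seed of the FOXM1 siRNA, genes with the word CCTCGGC lay -1.543 standard errors from the rest in the held-out genes, and the word AGATGAA, chosen on the other set, gave -3.19, so a seed effect stays open. CCTCGGC stands in 0 of the 4 annotated coding transcripts of FOXM1, which argues against that word as the seed site but leaves other words open, and AGATGAA stands in 4 of the 4. For ITFG2, 0 of 1 annotated 3' UTR holds the word CCTCGGC, which excludes nothing because that word was not established as the seed. ITFG2 and FOXM1 share 781 exonic bases, 15.9% of FOXM1's 4899; ITFG2 fell by 748 normalized counts, 21.9% of FOXM1's fall, with log2 slopes on FOXM1 of 0.91 without and 0.12 with siFOXM1, so FOXM1 reads counted to ITFG2 could account for its fall or not. The neighbour RHNO1, with 0 exonic bases shared with FOXM1, stood at log2 0.12 with siFOXM1 (limma adjusted p = 0.934, with the block 0.412), which leaves this open.

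The last pattern is the 21 genes lower, with the block, in siCENPF than in siNeg and in both siRNAs than in siFOXM1, with medians against siNeg of log2 -0.51 and -0.33 (0.04 with siFOXM1); its test was set before the result was seen. For a seed of the CENPF siRNA, held-out genes with the word AGCGCTA lay -2.603 standard errors from the rest, between the 2 limits set for excluding and accepting a seed effect, so this stays open. Only 46 held-out genes hold this word, fewer than hold the simulated words. The other set of genes chose ACTTTTA, with -0.669. AGCGCTA and ACTTTTA each stand in 1 of the 2 annotated coding transcripts of CENPF, which decides nothing. The word AGCGCTA stands in 7 of 20 searched pattern genes (1.04% of all searched genes), among them HIF1AN, OSTM1 and C3orf38. It stands in 0 of the 9 that were held out (0.786% of all held-out genes). Over all genes, including those used for the choice, AGCGCTA and the shifted word GCGCTAA lay -4.92 and -4.66 standard errors from the rest. For siCENPF against siNeg, in place of both siRNAs against siFOXM1, held-out genes with AGCGCTA lay -3.52 standard errors from the rest.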

How the results depend on the processing

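The falls of CENPF and FOXM1 kept direction and call under every alternative run, and no result reversed. Of 71 named values, all kept direction and call with pseudocounts of 0.1 and 5, a minimum of 100, no filter, TMM and median of ratios; edgeR lost 3 calls and FPKM values 18, with no FPKM value for 1 gene. With 1 library left out, 317 calls were kept and 121 lost. With FPKM values 10 of the 35 list calls were lost, with camera adjusted p from 0.0536 to 0.0793: YAP/TAZ targets with siCENPF, FOXM1 targets with siFOXM1, cohesin and G2/M genes with both siRNAs, S phase genes for both against siFOXM1, the spindle checkpoint, YAP/TAZ targets and cholesterol synthesis for both against siCENPF, and FOXM1 targets and G2/M genes in the interaction. The block ended 0 calls of the named values and of the 35 lists, but genes named for one comparison can pass with it in others, where no value of theirs is given. Limma without the block recovered 52% of simulated 1.5-fold changes, so smaller effects could go undetected.

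Counts of genes called are given in the order siCENPF, siFOXM1 and both siRNAs against siNeg, both against siFOXM1, both against siCENPF, and the interaction (50, 98, 68, 1, 12 and 0). With the replicate block they were 671, 1295, 1174, 44, 217 and 125, the F test called 1758 genes in place of 118 and camera 59 lists in place of 35; the median residual SD fell from 0.190 to 0.119. DESeq2 on recovered reads called 138, 249, 165, 4, 33 and 22 (the cause was not tested). Limma without trend and robust moderation called 26, 61 and 41 against siNeg (the cause was not tested). A fit to the compared libraries alone called 6, 41 and 35 against siNeg and 3 for both against siCENPF, with fewer libraries to estimate the spread. A log2 fold change over 1 left 10, 18 and 13 against siNeg and 5 for both against siCENPF (16, 43, 30 and 8 with the block). The F test on the FPKM table called 76 genes (the cause was not tested). Leaving out 1 library gave 21 to 29, 34 to 55, 30 to 43, 1 to 1, 2 to 11 and 0 to 0, with fewer libraries in each. For siCENPF, leaving out siNeg library 1, 2 or 3 gave 25, 21 and 22, and siCENPF library 1, 2 or 3 gave 28, 25 and 29. For siFOXM1, leaving out siNeg library 1, 2 or 3 gave 51, 55 and 44, and siFOXM1 library 1, 2 or 3 gave 50, 48 and 34. For both siRNAs, leaving out siNeg library 1, 2 or 3 gave 43, 30 and 35, and library 1, 2 or 3 of both siRNAs gave 32, 41 and 34. Against siCENPF, leaving out siCENPF library 3 gave 4, and library 1 or 3 of both siRNAs 6 and 2.

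Of the 35 list calls, 0 held with an estimated correlation, as did 0 of the 59 with the block, 0 lists passed the directional fry test, 4 the mixed one and 15 the directional one with the block; fry does not compare a list with other genes (the cause was not tested). Among genes with a mean of at least 100 normalized counts, r was 0.479 for siCENPF and siFOXM1, 0.688 for siCENPF and both siRNAs and 0.815 for siFOXM1 and both (0.498, 0.497 and 0.497 in simulations of unchanged groups with the same controls; the cause was not tested). The shared control mean alone sets these simulated values. Further alternatives with the block were chosen after seeing the data. Leaving out all libraries of a replicate number gave 290 to 626, 513 to 1122, 469 to 1084, 5 to 26, 63 to 239 and 30 to 109, with fewer libraries in each; without number 1 the counts were 290, 673, 539, 5, 63 and 30, without number 3 353, 513, 469, 15, 104 and 44, and without number 2 26 for both against siFOXM1. With the block, edgeR called 672, 1289, 1187, 30, 218 and 104, and limma on thinned reads 662, 1189, 1109, 39, 216 and 117.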

Other observations

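Interferon-stimulated genes differed between the replicate numbers far more than between the siRNA groups. The 22 measured members had a median log2 deviation from the group means of 2.23 in libraries numbered 1, -1.08 in those numbered 2 and -1.20 in those numbered 3, a spread of 3.43 and the largest of the 23 lists. This comparison was chosen after seeing the data. IFIT1, an antiviral effector, stood in number 1 at 7430 normalized counts in siNeg, 10091 in siCENPF, 2994 in siFOXM1 and 3471 with both siRNAs, and at 110 to 349 in the other 8 libraries. ISG15 stood at 3179, 3885, 1295 and 1368 in number 1. Between the highest and the lowest number OAS2 differed 124-fold, MX2 75.1-fold and OAS1 40.5-fold (limma adjusted p = 0.000661, 0.000226 and 0.000394).

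Integrated stress genes deviated by 0.50, -0.39 and -0.07 in numbers 1 to 3, cholesterol synthesis genes by -0.35, 0.31 and 0.03, and senescence-associated secretory genes by 0.45, -0.21 and -0.21. In all, limma found 6894 of 14857 genes (46.4%) that differed between the 3 replicate numbers. In the FPKM table, 45417 genes stand outside the normalized count table, and 1304 of them could be tested. Limma called 0 of these in each comparison, without and with the block; 40, 68 and 65 had an unadjusted p under 0.05 for siCENPF, siFOXM1 and both siRNAs, and no other tool was run on them.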
